A study of Homo sapiens with 15 samples.

How the data were processed

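Bulk RNA was sequenced from 15 libraries of retinal organoids grown from H1, an established human embryonic stem cell line. There are 5 time points with 3 libraries each, and the groups and replicate numbers were taken from the sample labels. Per the labels, libraries were made from total RNA with a strand-specific kit. The deposited files hold counts per gene symbol, 1 file per library, written by HTSeq. The authors name CASAVA, TopHat2 and HTSeq without versions, the genome build hg19 (GRCh37), and DESeq2 1.10.1 for later steps. The annotation release, the strand setting and any read filter are not given in the sources used here. The values are whole numbers, and the closing lines of each file, which count reads given to no gene, were kept out of the gene table and used for quality only. Genes are named by symbol as in the files. No positions are given, because the annotation at hand (GENCODE v29) is for another genome build; it served only to compare transcript sequences.

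The files hold 23228 genes, of which 21256 had a count in at least 1 library. Counts assigned to genes ranged from 7904561 to 33180565 per library. Genes were kept by filterByExpr over the 5 groups, which left 17093. Libraries were scaled by TMM, with factors from 0.863 to 1.09. Levels are given as CPM, read counts scaled to a common library size with edgeR's cpm function, not corrected for gene length. A gene with 0 counts in a library could still have up to 3 counts by counting error, which is 0.105 to 0.366 CPM depending on the library; intervals and limits of this kind cover counting error only.

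Differences were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, in a single model with 1 mean per time point, so that all 15 libraries share the estimate of the spread (10 residual degrees of freedom, biological coefficient of variation 0.15). The 4 contrasts compare neighbouring time points, and a further F test asks whether a gene changes at all over the 5 time points. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested and called below 0.05. The genes that changed anywhere were counted by the time point of their highest mean. On data simulated with known changes the procedure was tested before use, with genes that vary independently of each other.

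Before the data were examined, 38 gene lists were fixed for retinal cell classes, the cell cycle, cell types that do not belong to the retina, metabolism, stress, and library type. For each list and contrast the members called higher and lower were counted, also adjusted over the list alone. Each list was tested with camera in limma 3.58.1 with the preset correlation of 0.01 between genes, adjusted over the 152 combinations of list and contrast, again with a correlation estimated per list, and with fry, which asks whether the members move, on balance, in 1 direction. Where a value is called camera adjusted p, it comes from the preset correlation. For a summary of cone against rod genes, the mean of log2(CPM + 1) over the rod list was subtracted from that over the cone list in each library, and the 6 libraries of 6.5 and 9 months were compared with the 3 of 3 months by an exact 2-sided permutation test over 84 splits.

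The named genes follow a rule fixed before the data were examined. In each contrast it takes the 6 largest rises and the 6 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups, leaving out uncharacterised loci, small and antisense RNAs, XIST and TSIX, and genes of the Y chromosome. It adds the 3 members with the highest mean of the lists that matter most for the contrast, the 2 highest of any other list described, 12 fixed marker genes followed through all contrasts, not all of which are described, and called members that go against their list. Genes outside the rule are marked as chosen after their values were seen. OPN1LW, OPN1MW and OPN1MW2 are near-identical and their counts are uncertain.

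Alternatives planned before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a term for the replicate number, a term for the earlier culture day of the first replicate at 3, 6.5 and 9 months, library sizes without small non-coding RNA genes, a fold change of at least 2, only the 6 libraries compared, and leaving out each library of the groups compared. Chosen after seeing the data were thinning every library at random to the total of the shallowest, leaving out each library of the other time points, leaving out 2 libraries at 9 months together, and adjusting DESeq2's p-values over the genes tested with edgeR in the last step. DESeq2 otherwise ran on all genes with a count and adjusted over those that passed its own filter on mean counts. The labels do not say whether the 3 libraries of a time point come from separate cultures, so p-values measure the spread between libraries only. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.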

Results

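The series follows human retinal cultures of the H1 embryonic stem cell line, attached up to day 15 and then grown as retinal organoids, which are floating tissue aggregates, from 15 days to 9 months of culture, and its title names organoids rich in cones. Total RNA was sequenced at 15 days, 1 month, 3 months, 6.5 months and 9 months, with 3 libraries per time point. The labels give culture day 15 and day 30 for the first groups, days 85, 94 and 94 at 3 months, days 194, 195 and 195 at 6.5 months, and days 258, 259 and 259 at 9 months. Counts assigned to genes ranged from 30485819 to 33180565 per library at 15 days and from 21461850 to 28265940 at 1 month. They ranged from 10157746 to 17975548 at 3 months, from 7904561 to 25096664 at 6.5 months and from 16836918 to 24012622 at 9 months. All levels are mean CPM ± SD of the 3 libraries of a time point (n = 3) unless stated otherwise, and log2 changes are later minus earlier.

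Of the 17093 genes tested, 15110 (88.4%) changed somewhere over the 5 time points. By highest mean, 5410 of them peaked at 15 days, 2104 at 1 month, 2182 at 3 months, 1669 at 6.5 months and 3745 at 9 months. Within a time point the correlation of log2 CPM across genes was 0.971 to 0.996, and between 6.5 and 9 months it was 0.968 to 0.983. Genes are not independent replicates, so these values carry no test.

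**Figure D1:**
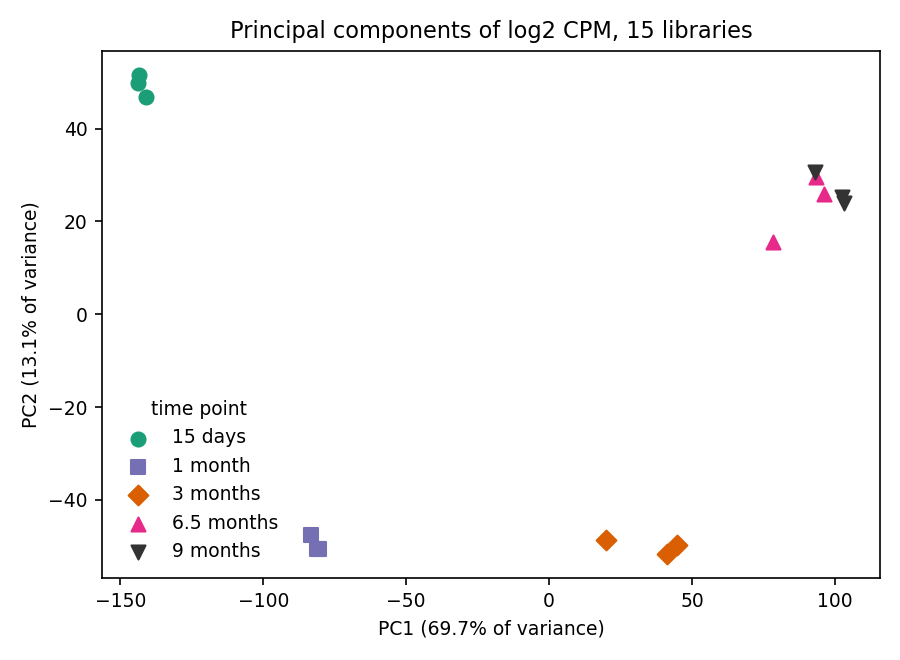
Principal components of log2 CPM over the genes tested. Each point is a library and colours and shapes mark the 5 time points; PC1 holds 69.7% and PC2 13.1% of the variance, and the 6.5- and 9-month libraries lie next to each other.

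The step from 15 days to 1 month starts at the stage that the series places before ganglion cell differentiation. Genes of early and dividing cells fell while genes of neurogenesis and ganglion cells rose. LIN28A, an RNA-binding protein of pluripotent cells and early progenitors, fell from 818 ± 21.7 to 9.83 ± 0.9 CPM. ATOH7, the transcription factor that opens the ganglion cell fate, rose from 0.368 ± 0.241 to 78.6 ± 7.93 CPM, and POU4F2, a ganglion cell transcription factor, rose from 0.134 ± 0.0484 to 77.9 ± 10.6 CPM. STMN2, a microtubule regulator of growing axons, rose from 4.08 ± 1.2 to 374.3 ± 54.4 CPM.

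Of 8 measured pluripotency genes 6 fell, and 7 adjusted over the list alone (camera adjusted p = 0.00156, adjusted p = 0.267 with an estimated correlation), while 1 rose with the replicate block. LIN28B fell from 294.5 ± 8.4 to 53.7 ± 4.83 CPM and the DNA methyltransferase DNMT3B from 185.5 ± 6.68 to 82.1 ± 3.84 CPM. In the G2 and mitosis list 17 of 18 members fell (camera adjusted p = 0.000872, adjusted p = 0.696 with an estimated correlation), among them the kinetochore gene CENPF from 1521 ± 116 to 616.5 ± 39.7 CPM and the proliferation marker MKI67 from 1145 ± 32 to 583 ± 14.4 CPM. TOP2A, at 1450 ± 23.2 and 987.4 ± 45 CPM, did not pass (adjusted p = 0.208). In the S phase list 13 of 16 fell (camera adjusted p = 0.0033, adjusted p = 0.698 with an estimated correlation), including the replication helicase genes MCM4 from 473.4 ± 5.93 to 291.5 ± 10.5 CPM and MCM7 from 452.7 ± 4.04 to 309.7 ± 18.1 CPM.

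Of 19 genes of neurogenic commitment 17 rose and none fell (camera adjusted p = 7.13e-11, adjusted p = 0.267 with an estimated correlation). ONECUT2 rose from 12.4 ± 2.73 to 235.8 ± 9.56 CPM and SOX4 from 547 ± 3.82 to 717.2 ± 10 CPM, while SOX11 was at 775.2 ± 8.47 and 706.5 ± 26.1 CPM and did not pass. Of 17 ganglion cell genes 14 rose (camera adjusted p = 1.77e-06, adjusted p = 0.295 with an estimated correlation), with the neurofilament genes NEFM from 12.6 ± 5.94 to 164.6 ± 14.6 CPM and NEFL from 11.9 ± 3.55 to 157.1 ± 28.7 CPM. The 3 that fell were the RNA-binding protein genes RBPMS, from 52.1 ± 4.34 to 26.6 ± 2.33 CPM, and RBPMS2, from 36.9 ± 0.828 to 22.1 ± 0.786 CPM, and the cell surface gene THY1, from 29.2 ± 2.72 to 8.21 ± 2 CPM. Amacrine genes rose in 10 of 14 members and fell in 1 (camera adjusted p = 0.000172, adjusted p = 0.267 with an estimated correlation). That was the homeobox gene MEIS2, from 138.8 ± 8.04 to 105.5 ± 6.17 CPM, though no member fell with upper-quartile scaling or without 15-day replicate 1 or 1-month replicate 3. The glycine transporter gene SLC6A9 did not pass, at 17.9 ± 1.58 and 18.8 ± 1.33 CPM. Horizontal cell genes rose in 7 of 9 (camera adjusted p = 0.000609, adjusted p = 0.267 with an estimated correlation), with ONECUT2 among them. The tropomyosin gene TPM3 fell from 331.4 ± 11.6 to 195.8 ± 4.02 CPM.

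Among the 17 eye field and progenitor genes 4 rose and 3 fell (camera adjusted p = 0.623). PAX6, a master regulator of eye development, rose from 541.7 ± 13.6 to 1033 ± 53.8 CPM. The Wnt pathway genes SFRP2, from 3355 ± 214 to 2621 ± 37.5 CPM (adjusted p = 0.0484), and FZD5, from 1344 ± 124 to 1046 ± 46.7 CPM (adjusted p = 0.0354), passed narrowly. SFRP2 did not pass when any 1 of the 6 libraries compared was left out, nor without 3-month replicate 2 or 3 or 6.5-month replicate 1. It also did not pass with RLE scaling, upper-quartile scaling, the culture-day term, the replicate block or thinning, at log2 changes of -0.34, -0.21, -0.36, -0.36 and -0.32. FZD5 did not pass without 15-day replicate 2 or 3 or any 1-month library, nor with upper-quartile scaling (-0.22) or thinning (-0.31). The count of falling members was 1 with thinning or without 15-day replicate 2 or 3 or 1-month replicate 2 or 3, and 5 without 3-month replicate 1. With upper-quartile scaling 6 rose and 1 fell, and the median log2 change of the list went from -0.05 to 0.09. Adjusted over the list alone 2 members of this list fell, and in the other lists described for this step the counts were those over all genes except where given.

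Photoreceptor genes were mostly still low, though many rose. CRX, the transcription factor of photoreceptor precursors, rose from 1.82 ± 0.25 to 24.9 ± 0.135 CPM, and NRL, the rod transcription factor, from 0.542 ± 0.215 to 1.77 ± 0.242 CPM, a call lost with limma-voom and with thinning. In the photoreceptor transcription factor list 8 of 14 rose, among them RORB from 9.81 ± 0.632 to 144.3 ± 17.7 CPM (camera adjusted p = 0.000423, adjusted p = 0.289 with an estimated correlation). OTX2 fell from 152.9 ± 17.6 to 80.2 ± 4.36 CPM, and SIX4 fell by 1.35 on the log2 scale (adjusted p = 1.94e-07). Outer segment genes rose in 17 of 33 members, and in 18 adjusted over the list alone (camera adjusted p = 1.62e-05, adjusted p = 0.587 with an estimated correlation), with CRB1 from 42.4 ± 8.79 to 297 ± 21.1 CPM. The 3 that fell were PROM1, a membrane gene of outer segment discs, by 0.53, the matrix gene IMPG1, by 1.63, and RGS9BP, which anchors a regulator of transducin, by 2.11 on the log2 scale. Of this list 11 rose and 1 fell with limma-voom, and 1 fell with upper-quartile scaling, with thinning or without 15-day replicate 2. Photoreceptor synapse genes rose in 11 of 15 members, and in 12 adjusted over the list alone (camera adjusted p = 3.25e-06, adjusted p = 0.31 with an estimated correlation), and the ribbon gene CTBP2 fell from 203.4 ± 7.37 to 143.8 ± 1.45 CPM. Of 12 cone genes 5 rose (camera adjusted p = 0.00647, adjusted p = 0.664 with an estimated correlation), 8 with DESeq2 or without 6.5-month replicate 1 and 3 with thinning, with GNB3 from 14.5 ± 0.088 to 25 ± 2.56 CPM. Of 13 rod genes 2 rose (camera adjusted p = 0.319), 4 with DESeq2 and 0 with limma-voom or thinning. The short-wavelength opsin gene OPN1SW rose from 0.169 ± 0.0147 to 0.874 ± 0.302 CPM, but did not pass without 1-month replicate 1, at a log2 change of 2.02, or with thinning, at 3.00. Not called were ARR3 (2.09 ± 0.162 and 1.8 ± 0.12 CPM), GNAT2 (1.53 ± 0.672 and 3.07 ± 0.302 CPM), GNAT1 (0.263 ± 0.159 and 1.17 ± 0.0312 CPM) and RLBP1 (0.571 ± 0.131 and 0.879 ± 0.192 CPM). GNAT2 passed as higher without 15-day replicate 2, 6.5-month replicate 1 or 9-month replicate 1, with log2 changes of 1.34, 0.99 and 0.99. GNAT1 passed without 3-month replicate 1, with 2.11. Both also passed with DESeq2 and with only the 6 libraries of this step, GNAT2 with upper-quartile scaling, and RLBP1 with only the 6 libraries. OPN1LW had 0 counts in all 6 libraries.

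Genes of the lens, a tissue outside the retina, rose as well. Of 13 measured lens genes 11 rose (camera adjusted p = 5.03e-05, adjusted p = 0.489 with an estimated correlation), and 1 fell adjusted over the list alone, with limma-voom or thinning, or without 1-month replicate 3. The crystallin gene CRYAA rose from 15.1 ± 2.16 to 1039 ± 575 CPM. Among the largest rises were the crystallin genes CRYBB1, from 0.566 ± 0.119 to 289.8 ± 147 CPM, CRYBA4, from 0.694 ± 0.215 to 172.4 ± 87 CPM, and CRYBA2, from 0.0236 ± 0.0205 to 18.6 ± 8.49 CPM. The 1-month libraries differed in CRYAA, with 402.5 CPM in replicate 1, 1520 CPM in replicate 2 and 1195 CPM in replicate 3. HOX genes of hindbrain and spinal cord rose in 11 of 14 members and in 12 adjusted over the list alone (camera adjusted p = 0.00369, adjusted p = 0.668 with an estimated correlation), with HOXB3 from 0.217 ± 0.156 to 20.3 ± 12.2 CPM and HOXB2 from 0.349 ± 0.477 to 8.76 ± 4.9 CPM. That count was 7 without 15-day replicate 2 or 3 or 1-month replicate 1 or 2. Also among the largest rises were CHRNB3, a nicotinic receptor subunit, from 0.0127 ± 0.0219 to 10.02 ± 3.79 CPM, and the transport protein gene TTR, from 0.0359 ± 0.0622 to 10.4 ± 10.8 CPM. At 15 days these genes had 1 to 3 counts in all, as had CRYBA2, and the ratios were 808 (95% counting interval 145 to 31966) for CHRNB3, 286 (97.4 to 1389) for TTR and 738 (204 to 6102) for CRYBA2.

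The other largest falls were genes of contractile and matrix proteins and a forebrain transcription factor. ACTC1, a cardiac actin, fell from 69.8 ± 21.9 to 0.866 ± 0.221 CPM, ANKRD1 from 101 ± 19 to 2.03 ± 0.498 CPM, and FEZF1 from 28.5 ± 3.6 to 1.1 ± 0.389 CPM. The matrix glycoprotein gene TNC fell from 172.5 ± 6.32 to 6.77 ± 0.931 CPM and the collagen gene COL12A1 from 111.2 ± 24.8 to 4.48 ± 0.66 CPM. Hypoxia response genes rose in 13 of 14 members (camera adjusted p = 1.87e-05, adjusted p = 0.489 with an estimated correlation), including the glucose transporter SLC2A1 from 168.3 ± 31.8 to 807.2 ± 75.2 CPM and P4HA1 from 112.4 ± 6.01 to 363 ± 60.7 CPM. Genes of oxidative phosphorylation fell in 17 of 23 (camera adjusted p = 0.000405, adjusted p = 0.489 with an estimated correlation), with ATP5A1 from 582.6 ± 11.9 to 452.7 ± 11.9 CPM and ATP5B from 560.4 ± 14.4 to 407.6 ± 9.56 CPM. With upper-quartile scaling 9 fell and 1 rose, and 1 rose with DESeq2, with thinning or without 3-month replicate 1.

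In all, 4121 genes were higher and 4938 lower at 1 month (edgeR). With upper-quartile scaling the split was 5213 higher and 3407 lower, and the median log2 change of all genes tested went from -0.04 to 0.10. Per the growth protocol, cultures were attached up to day 15 and grown floating and in serum later, so age and culture form change together in this step.

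From 1 to 3 months the photoreceptor genes came up and dividing cell genes fell further. CRX rose from 24.9 ± 0.135 to 698.8 ± 93.6 CPM and OTX2, which acts upstream of CRX, from 80.2 ± 4.36 to 735.2 ± 101 CPM. NRL rose from 1.77 ± 0.242 to 112.6 ± 29.6 CPM, and GNAT2, the cone transducin subunit, from 3.07 ± 0.302 to 67.5 ± 4.27 CPM. The ganglion cell genes ATOH7 and POU4F2 fell, from 78.6 ± 7.93 to 27.7 ± 23.2 CPM and from 77.9 ± 10.6 to 16.9 ± 18.8 CPM.

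Of 14 photoreceptor transcription factors 12 rose and SIX4 fell by 1.24 on the log2 scale (camera adjusted p = 3.65e-06, adjusted p = 0.267 with an estimated correlation). NEUROD1 was among those that rose, from 109.7 ± 7 to 592.6 ± 102 CPM. Of 12 measured cone genes 10 rose (camera adjusted p = 7.17e-07, adjusted p = 0.382 with an estimated correlation). Among them were GNB3 from 25 ± 2.56 to 674.1 ± 125 CPM, PDE6H, a cone phosphodiesterase subunit, from 1.89 ± 0.467 to 216.6 ± 21.2 CPM, and the cone arrestin ARR3 from 1.8 ± 0.12 to 30.7 ± 10.5 CPM. OPN1SW was not called (0.874 ± 0.302 and 0.935 ± 0.503 CPM) and OPN1LW had 0 counts at both time points. Of 13 rod genes 11 rose, and 7 with limma-voom (camera adjusted p = 6.5e-06, adjusted p = 0.413 with an estimated correlation). PDE6B rose from 30.3 ± 2.03 to 83.6 ± 12.1 CPM and the rod transducin GNAT1 from 1.17 ± 0.0312 to 55.3 ± 31.8 CPM.

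Outer segment genes rose in 30 of 33 members (camera adjusted p = 2.84e-17, adjusted p = 0.289 with an estimated correlation), and CRB1, a polarity gene, fell from 297 ± 21.1 to 203.1 ± 46.5 CPM. Without 3-month replicate 2 no member fell. IMPG2 rose from 23.7 ± 6.67 to 1319 ± 153 CPM and CDHR1 from 26.6 ± 2.72 to 754.8 ± 117 CPM. Among the largest rises were the axoneme gene RP1 (0.305 ± 0.112 to 273.3 ± 107 CPM), the disc rim gene PRPH2 (0.201 ± 0.13 to 112.6 ± 31.3 CPM) and MPP4 (1.14 ± 0.381 to 263 ± 44.9 CPM). GUCA1C, a guanylate cyclase activator, went from 0 counts to 20.8 ± 14.9 CPM, at least 458-fold higher with 3 counts over the group as the floor. SAMD7 went from 1 count to 23.5 ± 12.2 CPM, a ratio of 1567 (95% counting interval 281 to 61951). Synapse genes of photoreceptors rose in 14 of 15 members (camera adjusted p = 5.24e-09, adjusted p = 0.267 with an estimated correlation), with SYP from 24.9 ± 2.94 to 304.9 ± 13.6 CPM and CTBP2 from 143.8 ± 1.45 to 185.4 ± 6.72 CPM.

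Genes of the inner retinal classes went both ways. Amacrine genes rose in 9 of 14 members (camera adjusted p = 0.00613, adjusted p = 0.31 with an estimated correlation), among them TFAP2A from 3.01 ± 0.21 to 74.5 ± 17.7 CPM, MEIS2 from 105.5 ± 6.17 to 232.1 ± 48.1 CPM and SLC6A9 from 18.8 ± 1.33 to 39.2 ± 7.13 CPM. None fell, against 1 with thinning or without 3-month replicate 2. Bipolar genes rose in 10 of 16 members and fell in 1 (camera adjusted p = 0.00137, adjusted p = 0.267 with an estimated correlation), with CABP5 from 2.81 ± 0.368 to 103.9 ± 38 CPM. Without 3-month replicate 1, 2 members fell. Ganglion cell genes split into 3 that rose and 4 that fell of 17 (camera adjusted p = 0.343), and 7 fell with limma-voom. Without 3-month replicate 1, 2 rose and 9 fell. INA, an intermediate filament gene, rose from 131.6 ± 25.3 to 335.8 ± 35.8 CPM. STMN2 was at 374.3 ± 54.4 and 415.9 ± 80.4 CPM and NEFM at 164.6 ± 14.6 and 98.8 ± 95.1 CPM without a call. NEFM was 208.6 CPM in 3-month replicate 2 and passed as lower without that library, by -1.91 on the log2 scale. Horizontal cell genes split into 2 higher and 4 lower of 9 (camera adjusted p = 0.57). SEPT4 rose from 28.7 ± 3.42 to 322.9 ± 46.5 CPM, and ONECUT2 and TPM3 fell, to 113.5 ± 11.7 and 153.4 ± 6.14 CPM. Genes of neurogenic commitment split into 6 and 7 of 19 (camera adjusted p = 0.985). SOX4 rose to 876.6 ± 35.6 CPM and SOX11 fell to 401.6 ± 64.5 CPM. RLBP1, a Müller glia gene of the visual cycle, rose from 0.879 ± 0.192 to 31.2 ± 4.69 CPM.

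Progenitor genes fell in 12 of 17 members (camera adjusted p = 0.000118, adjusted p = 0.295 with an estimated correlation). SFRP2 fell from 2621 ± 37.5 to 201 ± 12.6 CPM and PAX6 from 1033 ± 53.8 to 751.8 ± 49.7 CPM. The 2 that rose were of the Notch pathway, NOTCH1 from 196.9 ± 10.5 to 428.5 ± 34.4 CPM and HES5 from 14.2 ± 0.394 to 34.4 ± 23.7 CPM. The count of rising members was 1 with the culture-day term and when any 1 of the 1-month libraries or 3-month replicate 1 was left out. All 18 G2 and mitosis genes fell (camera adjusted p = 9.1e-07, adjusted p = 0.519 with an estimated correlation), including TOP2A to 271.8 ± 177 CPM, MKI67 to 215 ± 92.9 CPM and CENPF to 170.2 ± 77.4 CPM. All 16 S phase genes fell as well (camera adjusted p = 3.39e-06, adjusted p = 0.501 with an estimated correlation), with MCM7 at 135.6 ± 24 CPM and MCM4 at 110.8 ± 39.6 CPM at 3 months. Lens genes fell in 11 of 13 members and in 12 adjusted over the list alone (camera adjusted p = 0.000405, adjusted p = 0.519 with an estimated correlation), with CRYAA down to 42.6 ± 26.3 CPM and CRYBB1 down to 20.3 ± 13.3 CPM, and 1 rose without 3-month replicate 3. In the other lists described for this step the counts adjusted over the list alone were those over all genes.

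The largest falls were MAGEA4, from 11.1 ± 1.65 CPM to 0 counts, at least 159-fold lower with the same floor. The others were BHMT, an enzyme of methionine metabolism (104.3 ± 73.8 to 0.593 ± 0.516 CPM), VIT (16.4 ± 11.3 to 0.114 ± 0.135 CPM), the neuropeptide NTS (16.3 ± 1.21 to 0.157 ± 0.156 CPM), the Nodal inhibitor LEFTY2 (66.5 ± 29.6 to 0.832 ± 0.557 CPM) and the hyaluronan synthase HAS2 (124.2 ± 13.6 to 2.8 ± 0.865 CPM). In all, 4781 genes were higher and 4777 lower at 3 months. By its label, replicate 1 at 3 months was taken on day 85 and the others on day 94.

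**Figure D2:**
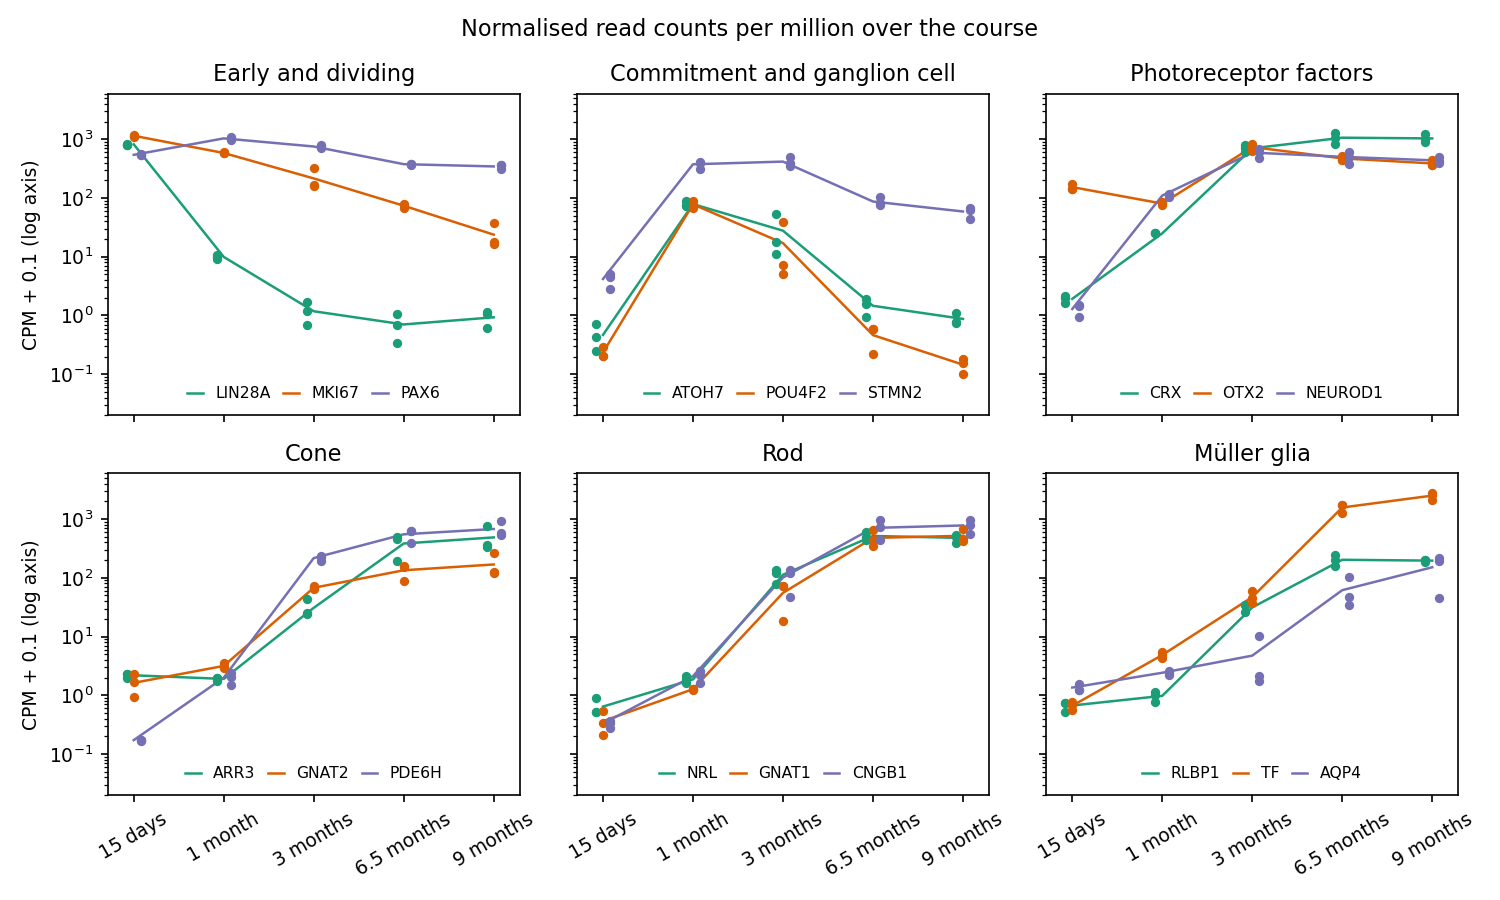
Normalised read counts of 18 genes at the 5 time points. Points are the 3 libraries of a time point, lines join the means, and the vertical axis is CPM + 0.1 on a log scale; ATOH7 and POU4F2 are highest at 1 month, and TF reaches a mean of 2507 CPM at 9 months.

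From 3 to 6.5 months rod, outer segment and Müller glia genes rose, and ganglion cell and cell cycle genes fell. SAG, the rod arrestin, rose from 0.939 ± 0.353 to 123.3 ± 73.4 CPM and GNAT1 from 55.3 ± 31.8 to 477.5 ± 155 CPM. ARR3, the cone arrestin, rose from 30.7 ± 10.5 to 383.5 ± 167 CPM. TF, the transferrin gene listed for Müller glia and also for liver, rose from 46.8 ± 11.1 to 1572 ± 247 CPM. POU4F2 fell from 16.9 ± 18.8 to 0.363 ± 0.212 CPM.

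All 13 rod genes rose (camera adjusted p = 5.24e-09, adjusted p = 0.289 with an estimated correlation). CNGB1, a channel subunit, rose from 100.9 ± 47.3 to 706.2 ± 254 CPM, NRL from 112.6 ± 29.6 to 515.2 ± 89.5 CPM, and the transducin subunit GNGT1 from 3.44 ± 3 to 183.5 ± 49.6 CPM. Of 12 cone genes 10 rose (camera adjusted p = 4.25e-05, adjusted p = 0.489 with an estimated correlation). GNB3 rose from 674.1 ± 125 to 1126 ± 94.9 CPM, PDE6H from 216.6 ± 21.2 to 550 ± 133 CPM, GNGT2 from 162 ± 50.5 to 490.8 ± 109 CPM and the cone opsin kinase GRK7 from 0.209 ± 0.239 to 12.2 ± 8.34 CPM. GNAT2 rose from 67.5 ± 4.27 to 134.3 ± 41.6 CPM, but did not pass without 6.5-month replicate 2 or 3, at log2 changes of 0.87 and 0.83. Of this gene, 24.9% of the 50-base windows of the transcript are found in no other gene on either strand, the others being shared with GNAI3. The search does not tell a near-identical copy from overlap on opposite strands, and an effect on the counts was not tested. The cone opsins stayed low, OPN1SW at 0.935 ± 0.503 and 2.07 ± 0.759 CPM without a call, and OPN1LW, whose counts are uncertain, at 0 counts and 0.151 ± 0.169 CPM, too few to be tested.

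Of 33 outer segment genes 30 rose and none fell, against 1 without 3-month replicate 1 (camera adjusted p = 7.13e-11, adjusted p = 0.391 with an estimated correlation). IMPG2 rose from 1319 ± 153 to 2312 ± 382 CPM, CDHR1 from 754.8 ± 117 to 1490 ± 278 CPM and recoverin, RCVRN, from 516 ± 160 to 1467 ± 240 CPM. CRX rose to 1061 ± 234 CPM. Bipolar genes rose in 11 of 16 members and in 12 adjusted over the list alone (camera adjusted p = 0.000373, adjusted p = 0.267 with an estimated correlation). CABP5 rose from 103.9 ± 38 to 363.2 ± 71 CPM. The glutamate receptor of ON bipolar cells, GRM6, fell from 89.6 ± 9.46 to 68 ± 7.86 CPM (adjusted p = 0.0339) and the transcription factor LHX4 from 31.4 ± 3.04 to 19.5 ± 4.15 CPM. GRM6 did not pass without 3-month replicate 2 or 3 or 6.5-month replicate 1 or 3, and the count of falling members was 1 without the first 3 of these libraries and 0 without 6.5-month replicate 3. With thinning GRM6 was not called and 1 member fell. Müller glia genes rose in 14 of 17 members and in 15 adjusted over the list alone (camera adjusted p = 1.04e-09, adjusted p = 0.267 with an estimated correlation). RLBP1 rose from 31.2 ± 4.69 to 202.6 ± 44.7 CPM and DKK3 from 624.6 ± 11.9 to 1177 ± 171 CPM, while VIM, at 1456 ± 102 and 2016 ± 375 CPM, was not called. It passed with DESeq2, with the 6 libraries of this step alone, and without 9-month replicate 1 or 3.

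Markers of other cell types rose in this step as well. Astrocyte genes, of which AQP4 is also in the Müller glia list, rose in 5 of 11 members, the same count adjusted over the list alone (camera adjusted p = 0.0373, adjusted p = 0.587 with an estimated correlation), and in 3 without 3-month replicate 1 or 3 or 6.5-month replicate 3. The glutamate transporter gene SLC1A2 rose from 152.4 ± 20.8 to 215.5 ± 14.9 CPM, and among genes chosen after their values were seen GFAP rose by 3.20 and the water channel gene AQP4 by 3.75 on the log2 scale. SLC1A2 and GFAP did not pass without any 1 of those 3 libraries, nor GFAP with limma-voom. FABP7 did not pass, at 171 ± 34.3 and 137.4 ± 42.5 CPM. ALDH1A1, a retinaldehyde dehydrogenase, fell by 2.02, but did not pass with limma-voom, with the 6 libraries of this step alone, or without 3-month replicate 1 (-0.17) or any 6.5-month library.

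Pigment epithelium genes rose in 11 of 17 members (camera adjusted p = 0.00202, adjusted p = 0.519 with an estimated correlation). SERPINF1 rose from 104.3 ± 17.3 to 177.7 ± 28.3 CPM, and the melanin synthesis gene DCT fell from 193.3 ± 40.6 to 26.5 ± 9.42 CPM, though no member of the list fell with DESeq2. Choroid plexus genes, of which TTR is also in the pigment epithelium list, rose in 5 of 11 members, the same count adjusted over the list alone. The list passed narrowly by camera (camera adjusted p = 0.047, adjusted p = 0.489 with an estimated correlation). It did not pass by camera with the replicate block (adjusted p = 0.0575). The water channel gene AQP1, chosen after its values were seen, rose from 7.58 ± 4.38 to 73.2 ± 28.9 CPM, and the prolactin receptor gene PRLR fell from 11.3 ± 5.19 to 3.34 ± 0.628 CPM. IGFBP2, at 145.4 ± 43 and 205.6 ± 151 CPM, and SLC4A5, at 49.2 ± 7.64 and 69.8 ± 19.9 CPM, did not pass. Complement and interferon genes rose in 9 of 16 members and in 11 adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.668 with an estimated correlation), and in 14 without 9-month replicate 1. B2M, part of the class I antigen complex, rose from 47.1 ± 5.6 to 156.2 ± 3.7 CPM. The remaining largest rises were the protease inhibitor SERPINA3 (1.62 ± 0.819 to 95.2 ± 30 CPM), the collagen COL15A1 (1.01 ± 0.496 to 57.8 ± 14.2 CPM) and C21orf7 (0.232 ± 0.0658 to 11.1 ± 3.09 CPM).

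Ganglion cell genes fell in 14 of 17 members (camera adjusted p = 5.35e-06, adjusted p = 0.31 with an estimated correlation), 15 adjusted over the list alone, where 1 rose. STMN2 fell from 415.9 ± 80.4 to 86.9 ± 13.4 CPM, INA from 335.8 ± 35.8 to 242.2 ± 34.5 CPM and POU4F1 from 19.99 ± 13.9 to 0.941 ± 0.14 CPM. Over all genes 1 member rose without 3-month replicate 1, with DESeq2, limma-voom or the culture-day term. Genes of neurogenic commitment fell in 14 of 19, and 15 adjusted over the list alone (camera adjusted p = 4.5e-07, adjusted p = 0.267 with an estimated correlation), SOX4 from 876.6 ± 35.6 to 490.7 ± 27.9 CPM and ATOH7 from 27.7 ± 23.2 to 1.36 ± 0.484 CPM. NEUROD1 was not called, at 592.6 ± 102 and 501.6 ± 117 CPM. G2 and mitosis genes fell in 16 of 18 members (camera adjusted p = 6.06e-05, adjusted p = 0.647 with an estimated correlation), TOP2A to 74 ± 8.17 CPM, MKI67 to 73.7 ± 4.71 CPM and CENPF to 60.2 ± 14.8 CPM. Lens genes fell in 12 of 13, and 6 with limma-voom (camera adjusted p = 0.000139, adjusted p = 0.489 with an estimated correlation), CRYAA to 5.98 ± 1.68 CPM, CRYBB1 to 4.36 ± 4.49 CPM and CRYBA4 from 13 ± 8.75 to 0.777 ± 0.653 CPM. CNTN2, an axonal adhesion molecule, fell from 132.2 ± 143 to 7.88 ± 2.66 CPM and the chloride channel ANO1 from 13.1 ± 7.02 to 0.387 ± 0.161 CPM.

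In the rod, cone, outer segment, pigment epithelium, G2 and mitosis, and lens lists of this step the counts adjusted over the list alone were those over all genes. In all, 3508 genes were higher and 3499 lower at 6.5 months. With the 6 libraries of this step alone the lower count was 2110.

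**Figure D3:**
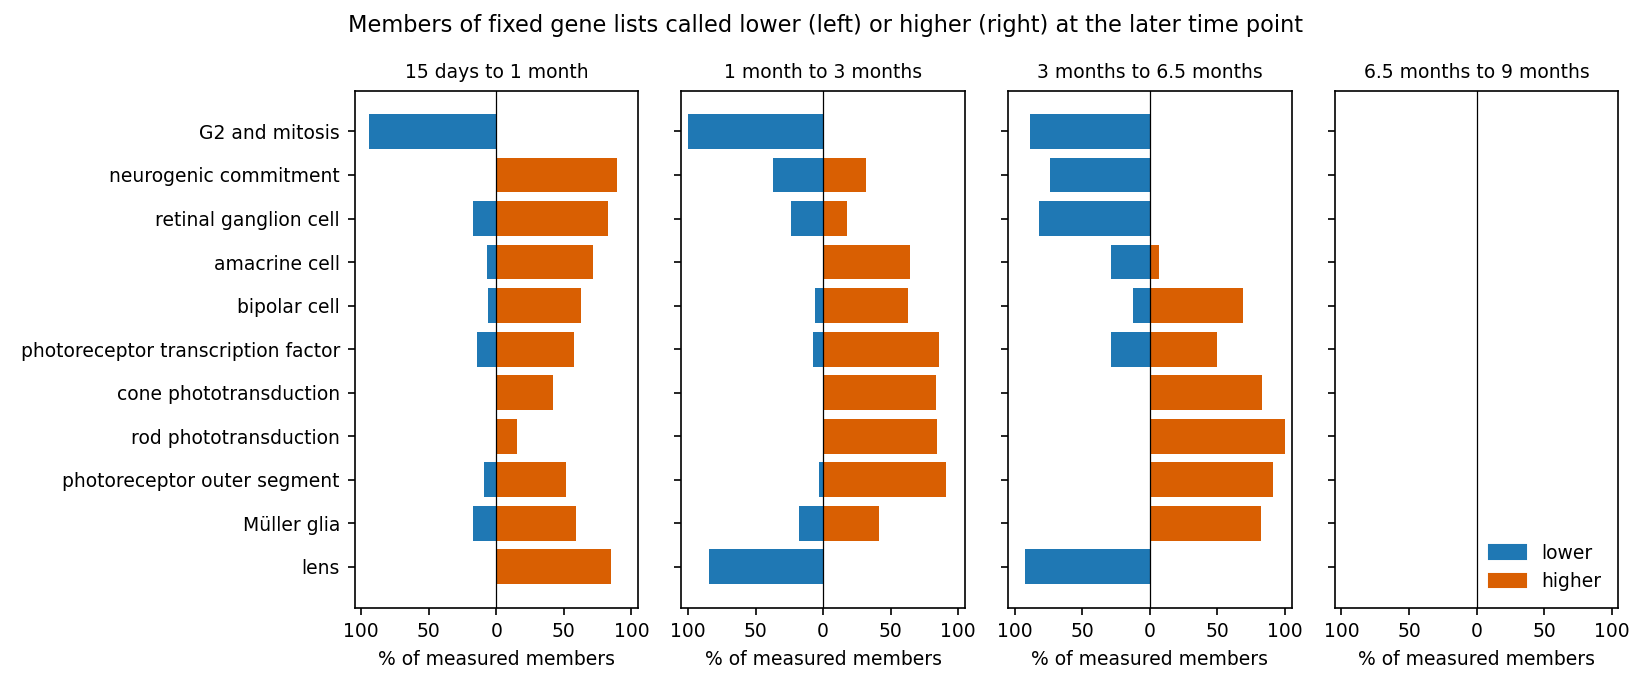
Share of the measured members of 11 gene lists called lower (blue, to the left) or higher (orange, to the right) at the later time point of each step, in percent. The calls are those of edgeR, which called no gene between 6.5 and 9 months, so the last panel is empty; DESeq2 called 60 higher and 217 lower there.

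Between 6.5 and 9 months no gene passed with edgeR. MKI67 was at 73.7 ± 4.71 and 23.7 ± 11.4 CPM (adjusted p = 0.109), TOP2A at 74 ± 8.17 and 28.2 ± 15.3 CPM (adjusted p = 0.187). MKI67 was called as lower by DESeq2, without 3-month replicate 1 and without 9-month replicate 3, with log2 changes of -1.66, -1.66 and -2.11, and TOP2A without the same libraries, with -1.40 and -1.93. TF was at 1572 ± 247 and 2507 ± 332 CPM (adjusted p = 0.133). TF was called by DESeq2, with the culture-day term and without 3-month replicate 1, with log2 changes of 0.66, 0.68 and 0.67.

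Adjusted over the list alone, 16 of 18 G2 and mitosis genes were lower (camera adjusted p = 2.58e-17, adjusted p = 0.289 with an estimated correlation), and over all genes 11 with DESeq2, 15 without 3-month replicate 1 and 7 without 9-month replicate 3. For S phase it was 9 of 16 adjusted over the list alone (camera adjusted p = 3.34e-08, adjusted p = 0.418 with an estimated correlation), and over all genes 2 with DESeq2, 5 without 3-month replicate 1 and 2 without 9-month replicate 3. RRM1 was at 76.3 ± 4.23 and 62.6 ± 3.61 CPM and MCM4 at 66.6 ± 5.87 and 47.2 ± 6.66 CPM.

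No photoreceptor gene passed with edgeR. None of the 12 cone genes was called over all genes or adjusted over the list alone (camera adjusted p = 0.431). GNB3 was at 1126 ± 94.9 and 1085 ± 218 CPM, PDE6H at 550 ± 133 and 677.3 ± 217 CPM, and GNGT2 at 490.8 ± 109 and 475 ± 180 CPM. ARR3 was at 383.5 ± 167 and 487.3 ± 243 CPM and GNAT2 at 134.3 ± 41.6 and 168.6 ± 80.4 CPM. OPN1SW was at 2.07 ± 0.759 and 1.91 ± 1.65 CPM and OPN1LW at 0.151 ± 0.169 and 0.0397 ± 0.0687 CPM. Of the 13 rod genes 1 was higher adjusted over the list alone (camera adjusted p = 0.0404, adjusted p = 0.742 with an estimated correlation), 1 was higher over all genes with DESeq2, and the median log2 change went from 0.41 to -0.04 without 9-month replicate 1. CNGB1 was at 706.2 ± 254 and 777.7 ± 200 CPM, GNAT1 at 477.5 ± 155 and 518.9 ± 127 CPM and NRL at 515.2 ± 89.5 and 477.1 ± 75.5 CPM. No outer segment gene (camera adjusted p = 0.056), photoreceptor synapse gene (camera adjusted p = 0.398) or pigment epithelium gene (camera adjusted p = 0.554) was called over all genes or adjusted over the list alone. IMPG2 was at 2312 ± 382 and 2501 ± 567 CPM, CDHR1 at 1490 ± 278 and 1509 ± 288 CPM, RCVRN at 1467 ± 240 and 1303 ± 172 CPM and CRX at 1061 ± 234 and 1032 ± 159 CPM. SV2B was at 667.6 ± 83.3 and 735.5 ± 119 CPM, CPLX4 at 407.7 ± 137 and 438.2 ± 109 CPM and SLC17A7 at 377.3 ± 42.5 and 409.8 ± 77.9 CPM. SERPINF1 was at 177.7 ± 28.3 and 163.4 ± 33.1 CPM, TYRP1 at 82.1 ± 28.5 and 96.3 ± 83.1 CPM and TTR at 55.2 ± 25.6 and 100.5 ± 63.5 CPM.

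Of 17 Müller glia genes 3 were higher adjusted over the list alone (camera adjusted p = 0.0388, adjusted p = 0.696 with an estimated correlation), and over all genes 2 with DESeq2, with the culture-day term or without 3-month replicate 1, and 1 without 9-month replicate 1. Without 9-month replicate 3, 1 was higher and 1 lower, and the median log2 change went from 0.21 to -0.02. Besides TF, VIM was at 2016 ± 375 and 1657 ± 588 CPM, DKK3 at 1177 ± 171 and 1130 ± 130 CPM and RLBP1 at 202.6 ± 44.7 and 195.9 ± 6.5 CPM. Against other genes, ganglion cell genes were lower by camera (camera adjusted p = 0.0034, adjusted p = 0.539 with an estimated correlation), as were genes of neurogenic commitment (camera adjusted p = 0.00674, adjusted p = 0.418 with an estimated correlation), but neither passed with fry (adjusted p = 0.223 and 0.0926). Adjusted over the list alone 0 of 17 and 2 of 19 were lower, and over all genes 1 neurogenic gene with the culture-day term or without 3-month replicate 1 or 9-month replicate 3, and 2 with DESeq2. ATOH7 was at 1.36 ± 0.484 and 0.774 ± 0.19 CPM and POU4F2 at 0.363 ± 0.212 and 0.0454 ± 0.0409 CPM.

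Reads aligned to several places were 52.1 and 72.3 per 100 gene counts in 9-month replicates 1 and 2, against 12.9 to 22.8 in the 13 other libraries. The list of non-coding RNAs of library type was higher at 9 months (camera adjusted p = 0.0337, adjusted p = 0.318 with an estimated correlation). Adjusted over the list alone 3 of 6 members were higher. Over all genes it was 3 with DESeq2 or without 9-month replicate 3 and 1 without 3-month replicate 1. The list members RPPH1 and RMRP were high in 9-month replicates 1 and 2 but not in replicate 3. MALAT1 was at 5914 ± 680 and 6173 ± 844 CPM and NEAT1 at 230.6 ± 12.9 and 347.7 ± 50.7 CPM. The replication-dependent histone list was higher by camera alone (camera adjusted p = 0.0182, adjusted p = 0.654 with an estimated correlation), did not pass with fry (adjusted p = 0.286) and had no member called except 4 without 9-month replicate 3. HIST1H1C was at 24.5 ± 8.66 and 31.0 ± 11.2 CPM and HIST1H2AC at 10.2 ± 3.39 and 10.8 ± 1.74 CPM.

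With fry 3 of the 38 lists passed in this step. They were the G2 and mitosis list (adjusted p = 0.013), the list of non-coding RNAs of library type (0.0291) and the patterning list (0.0317). By camera the patterning list was lower at 9 months (camera adjusted p = 0.0356). The eye field and progenitor list was lower by camera too (camera adjusted p = 0.00213), but did not pass with fry. Neither passed with an estimated correlation. The S phase, Müller glia and rod lists, which camera called, did not pass with fry (adjusted p = 0.0787, 0.291 and 0.403). In this step edgeR called 0 genes at a smallest adjusted p of 0.109, with 2126 at an unadjusted p below 0.05 where chance gives 854.6. DESeq2, which gave an adjusted p to 14245 of 21256 genes, called 60 higher and 217 lower (2180 unadjusted), or 59 and 199 when adjusted over the 17093 genes tested with edgeR, and limma-voom called 0 (2515 unadjusted). Without 9-month replicate 3 edgeR called 67 higher and 264 lower, without 9-month replicate 1 it called 15 and 1, without 6.5-month replicate 2 it called 0 and 1, and without 3-month replicate 1, which only shares the spread, it called 28 and 170.

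The balance of cone and rod genes shifted after 3 months. The cone minus rod level, over 12 cone and 13 rod genes, was -0.25 ± 0.05 at 15 days, 0.14 ± 0.08 at 1 month, 1.42 ± 0.13 at 3 months, 0.19 ± 0.27 at 6.5 months and -0.07 ± 0.05 at 9 months (log2, SD, n = 3). The cone mean itself was 5.01 ± 0.40 at 3 months and 6.93 ± 0.54 and 7.13 ± 0.48 at the later time points, and the rod mean was 3.59 ± 0.43, 6.74 ± 0.60 and 7.20 ± 0.44. Over 6.5 and 9 months together the difference was 0.06 ± 0.22 (n = 6), lower than at 3 months by -1.36 (exact 2-sided permutation p = 0.0119, the smallest that 84 splits allow). The difference was -2.51 with the median over list members, and all of its values under other settings were negative. All 6 late libraries were below all 3 libraries of 3 months. CPM is not corrected for gene length, so the level itself does not compare amounts of cones and rods.

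**Figure D4:**
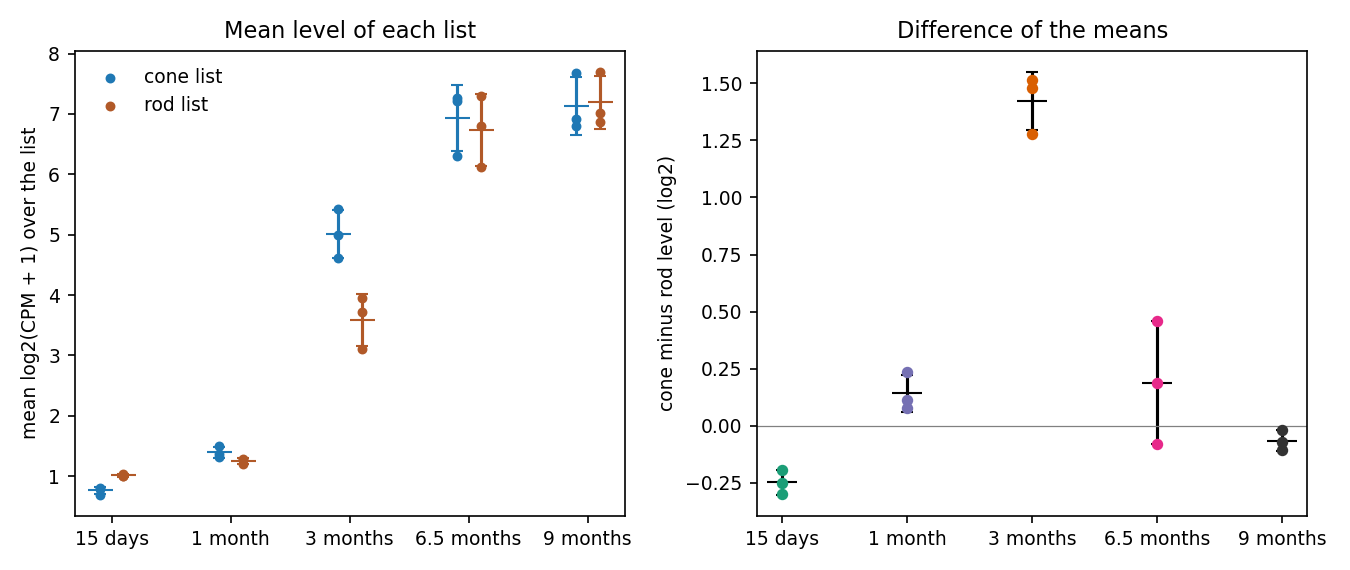
Mean log2(CPM + 1) of the cone and rod lists (left) and their difference (right) by time point. Points are libraries, bars show mean and SD of 3 libraries; the difference is 1.42 at 3 months and -0.07 at 9 months.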

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

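Of the tests in this part, leaving out both 9-month libraries at once, leaving out single libraries of other time points, thinning the libraries and comparing splits by unadjusted p were chosen only after the data were seen. Reads aligned to several places, which no comparison uses, stood at 72.31 per 100 gene counts in 9-month replicate 2 and 52.05 in 9-month replicate 1, above the 12.89 to 22.78 of the 13 other libraries. In the same 2 libraries the non-coding genes RPPH1 (106.7 and 177 CPM, against 0.739 CPM in replicate 3) and RMRP (47.9 and 77.4 CPM, against 0.398 CPM) were high; these genes were chosen after their values were seen.

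The pattern weighed here is that edgeR called 0 genes between 6.5 and 9 months, with 2126 at an unadjusted p below 0.05, while DESeq2 called 60 higher and 217 lower and limma-voom 0. Too few reads stays open for small changes. The step from 3 to 6.5 months called 91.1% as many genes (6380 against 7007) when every library was thinned to the total of the shallowest. That step held many large changes, 1361 genes higher and 921 lower by at least 2-fold, so the depth sufficed for those. Thinning it cannot tell whether small changes between 6.5 and 9 months were missed. In simulated data for the last step 20.9% of 1.5-fold changes were recovered, with every library given the spread of the 6 compared. The share may not hold for the real test, which shares the spread of all 15 libraries. Differences between libraries of a time point as large as that between the time points are consistent with the splits of the 6 libraries, since 3 of the 9 other splits had more genes at an unadjusted p below 0.05 (2285, 2544 and 3534) than the real one (2126). The highest of them, setting 6.5-month replicates 1 and 2 with 9-month replicate 3 against the rest, called 160 genes. It and the split with 2285 put both 9-month libraries rich in reads aligned to several places on 1 side, as the real split does. Of all 9 other splits 3 did so. The splits therefore cannot tell spread within a time point from a trait of these 2 libraries. The libraries rich in reads aligned to several places stay open, since 64 genes were called without both (with 1 library left at 9 months, assumed to vary like the other groups), 16 without replicate 1, 0 without replicate 2 and 331 without replicate 3, which has few such reads, and so does a small difference in age, which was not tested.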

How the results depend on the processing

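Of these alternatives, thinning, adjusting DESeq2 over the genes tested with edgeR, leaving out single libraries of time points not compared and leaving out both 9-month libraries rich in reads aligned to several places were chosen only after the data were seen. Requiring a fold change of at least 2 left 2215 genes higher and 831 lower from 15 days to 1 month, 2104 and 1592 from 1 to 3 months, and 1361 and 921 from 3 to 6.5 months, fewer by the rule itself. With only the 6 libraries compared, 2110 genes were lower from 3 to 6.5 months, while 5696 were higher and 5670 lower from 15 days to 1 month; the cause was not tested. Between 6.5 and 9 months, where edgeR called 0 genes, the culture-day term gave 2 higher and 8 lower, DESeq2 60 and 217 (59 and 199 adjusted over the genes tested with edgeR), and leaving out both 9-month libraries 63 and 1, with 1 library left at 9 months that is assumed to vary like the other groups; the cause was not tested. Leaving out single libraries gave 0 to 67 higher and 0 to 264 lower there, the highest without 9-month replicate 3, with 28 and 170 without 3-month replicate 1, 15 and 1 without 9-month replicate 1, and 0 and 1 without 6.5-month replicate 2. In simulated data for this step, where genes vary independently, 20.9% of 1.5-fold, 68.7% of 2-fold and 93.9% of 4-fold changes were recovered. All simulated libraries were given the spread of the 6 libraries compared, while the real fit shares the spread of all 15. These shares may therefore not hold for the real test. Of the 62 list calls by camera, 0 passed with an estimated correlation.

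Equal replicate numbers gave no sign of a shared origin, since correlations of residuals between them ran from -0.358 to 0.151. With 3 libraries per time point these values cannot exclude one. With the replicate block 4047 genes were higher and 4817 lower from 15 days to 1 month. For the other steps the replicate block gave 4644 and 4724, 3400 and 3333, and 0 and 0. Leaving out single libraries moved the cone minus rod difference to between -1.44 and -1.32, and it was -2.51 with the median over list members, -1.83 without NRL, NR2E3 and ESRRB, -1.49 with a pseudocount of 0.1 CPM and -1.16 without the opsins. A tally covered 138 combinations of gene and contrast, from the largest changes, the lists that matter most for a contrast and the fixed markers. Genes named from other lists were left out of it, such as SLC1A2 from 3 to 6.5 months and MKI67 and TOP2A in the last step. Within the tally, 3351 of 3447 alternative values were on the same side of the threshold and in the same direction. Of the rest, 33 no longer passed, 22 newly passed, and 41 turned direction without a call in either setting. Between 6.5 and 9 months lay 30 of these 41. Of values called in either setting, 0 turned direction. The shallowest library limits what low genes can show, since 3 counts there are 0.366 CPM.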

Other observations

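In this part the test of OPN1SW and the count of unique windows in OPN1MW were chosen only after the result was seen, and so were the genes named, apart from those the fixed rule also names. Complement and interferon genes were higher at 9 than at 6.5 months by camera (camera adjusted p = 0.0033, adjusted p = 0.68 with an estimated correlation) but not by fry (adjusted p = 0.344), with 4 of 16 members adjusted over the list alone and 0 over all genes. Over all genes 2 were higher with DESeq2 or without 9-month replicate 3, and 1 without 9-month replicate 1. The libraries of 9 months differed: B2M was at 75.7, 521.1 and 206.5 CPM in replicates 1, 2 and 3, and IFIT1, an interferon-induced gene, at 15, 112.4 and 21.1 CPM. The astrocyte gene GFAP was at 49.2, 1221 and 545.2 CPM and the water channel gene AQP4 at 45.6, 215.3 and 192.2 CPM.

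Patterning genes fell from 1 to 3 months in 11 of 17 members and in 12 adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.289 with an estimated correlation). BMP4, a dorsal signal, fell by 2.89 on the log2 scale. The signal FGF8 fell by 2.85 and the dorsal transcription factor TBX5 fell by 2.25. The 2 members that rose were the ephrin receptor gene EPHA5, by 0.84, and the T-box gene TBX3, by 0.67, and 1 rose with the replicate block, with the culture-day term or when any 1 of the 1-month libraries or 3-month replicate 1 or 3 was left out. General neuronal genes rose from 15 days to 1 month in 11 of 14 members (camera adjusted p = 2.61e-06, adjusted p = 0.267 with an estimated correlation), the same count adjusted over the list alone, with 1 falling without 6.5-month replicate 1. SNAP25, of the synaptic release machinery, rose by 2.74 and the microtubule gene MAPT by 2.88 on the log2 scale. KDR, a VEGF receptor listed for endothelium, was at 305.8 ± 43.1 CPM at 3 months, 485 ± 104 CPM at 6.5 months and 413.9 ± 36.7 CPM at 9 months, while the endothelial genes PECAM1 and CDH5 were at or below 3.21 CPM on average at these ages. In 3-month replicate 2, HOXB3 was at 73.9 CPM, HOXC4 at 37.1 CPM and NEFM at 208.6 CPM, against 1.42 and 6.82, 0.421 and 2.86, and 41.3 and 46.5 CPM in replicates 1 and 3.

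The opsin genes of long- and medium-wavelength cones were near 0 counts while other cone genes were high. Over the 6 libraries of 6.5 and 9 months OPN1LW averaged 0.0954 ± 0.131 CPM, with 13 counts in all, against 435 ± 195 CPM for ARR3. Reads lost between near-identical copies are argued against for OPN1LW only under assumptions that were not tested. These are even coverage of the transcript and, at its 5 stretches of unique windows, H1 bases equal to those of GENCODE v29. Under them, the 32.2% of its 50-base windows found in no other gene limit the loss to 3.11-fold and the mean to 0.296 CPM. The read length is not given in the sources used here. For OPN1MW (0.351 ± 0.155 CPM, n = 6) the 4.19% of unique windows would allow a loss of 23.9-fold, to 8.38 CPM, but they form 1 stretch, as 1 differing base would give, so the loss and a low level cannot be told apart. OPN1SW was low too, at 1.99 ± 1.15 CPM (n = 6), so RNA of the short-wavelength opsin was not high in their place. With the opsin genes of each kind low, this cannot tell which kind of cone was present. No biological explanation was tested beyond this.

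Replicate 1 at 3 months stood apart from replicates 2 and 3, with ATOH7 at 54.2 CPM against 11 and 17.8 CPM, POU4F2 at 38.6 against 5.01 and 7.19 CPM, and MKI67 at 322.2 against 163.5 and 159.2 CPM. Of the 776 genes at least 4-fold lower at 6.5 months than at 1 month, 61.1% were highest in replicate 1. An even division among the 3 libraries would give 33.3%, but genes are not independent replicates, so the comparison carries no test. After thinning to equal depth, with the genes chosen anew (711) and without TMM factors, the share was 58.5%. This argues against unequal counting error as the source. Thinning keeps the expected CPM of each gene, so other effects of deeper sequencing cannot be told from it. The earlier culture day on its label, 85 against 94, is consistent with these values, and a separate batch or culture, which the labels do not give, stays open.

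The splits of 6 libraries number 10 in each step, too few for a share under 0.05. The real split called 9059 genes from 15 days to 1 month and the highest other 0. From 1 to 3 months it was 9558 against 0, and from 3 to 6.5 months 7007 against 7; in each of these 1 split, the real one, called as many. From 6.5 to 9 months the real split called 0 and the highest other 160, and since every count is at least 0, the number of splits that reach the real one decides nothing. For any change over the 5 time points, 1 of 100 splits, the real one with 15110 genes, called as many, and the highest other called 8614. This argues against a random division of the libraries as the source of that count. It does not cover chance differences between cultures, as the labels do not say which libraries share one.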
